A study of Homo sapiens with 12 samples.

How the data were processed

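The series measured poly(A) transcripts by QuantSeq 3' mRNA sequencing, with single-end reads, in 12 libraries of OPM2 cells, 3 each for DMSO, JQ1, BKM120 and 18DS at 2 h. The only values used are the raw counts per Ensembl gene that the authors deposited as whole numbers, 1 column per library, with no normalization. Per the labels, the authors' processing named bcl2fastq 2.17.1.14, FastQC 0.11.5, cutadapt 1.7, HISAT2 2.1.0, SAMtools 1.9, featureCounts, Subread and limma, and the genome build hg19. The annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. The available annotation is of another build, so no coordinates are given. It served only for gene types, and symbols came from a list of gene names, which matched 51662 of 63152 identifiers and left 11490 without a symbol (5.54% of counts). Of the tested genes, 1366 had no symbol, 10371 were protein-coding and 1174 were pseudogenes.

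Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and data.table (version 1.17.8). Figures were drawn in Python 3.11.15 with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 13180. Library sizes were scaled by TMM, with factors of 0.971 to 1.033. One robust edgeR quasi-likelihood fit over the 12 libraries (common biological coefficient of variation 0.0862, prior degrees of freedom 27.3, residual degrees of freedom 8) tested 7 contrasts, the 6 pairs of groups and the departure of 18DS from the sum of the JQ1 and BKM120 changes on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Intervals are 95% confidence intervals from the fit. CPM values use the TMM-scaled library sizes for genes and the total counts for summed markers, and principal components used log2 CPM of tested genes.

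Gene lists were written from general knowledge before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. Of 28 lists, 25 had at least 3 tested genes and were tested with limma's camera at a preset correlation of 0.01, adjusted over 25 lists per contrast. The other 3 were markers of other cell types. Camera with an estimated correlation and the fry test were alternatives. List adjusted p-values below use the preset correlation unless another is named, and those with an estimated correlation were often larger. Of 1089 list entries 41 matched no identifier. Named genes are, per contrast, the 6 largest changes in each direction among called genes with a mean of at least 5 CPM and, in the pairwise contrasts, no overlap between the groups' libraries. They also include *MYC*, *HEXIM1*, *IRF4*, *CCND2*, *IRS2*, *PIK3IP1*, *TXNIP*, *BCL2L11*, *BCL2*, *MCL1*, *TUBB* and *TUBA1A* in every contrast. From each list with a camera adjusted p under 0.05 or at least 3 called members, the rule adds up to 4 members with the smallest adjusted p. *TXNIP* had 0 counts in the 12 libraries and was not tested.

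Overlaps of calls were set beside those of independent lists, and correlations and covariances of fold changes beside those of 100 simulations in which groups without changes shared 3 simulated DMSO libraries. All 12 libraries were simulated, with genes drawn independently of each other. Genes called in JQ1 or BKM120 against DMSO were tested again in 18DS against that compound, adjusted over those genes alone. The alternatives were library totals, upper-quartile and DESeq2 scaling, DESeq2's Wald test, limma-voom, dispersions without the robust option, other expression filters, protein-coding genes alone, thinning to the smallest library, a replicate block, and each library left out in turn. Some identifiers share reads, since 46 tested genes in 23 sets had identical counts and *EEF1A1* (830578 counts) and its pseudogene *EEF1A1P5* (810357 counts) were nearly equal. Named genes were checked for another identifier within 5% of their counts in every library.

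The test was checked on simulated data with the depths of the 12 libraries and the dispersions of their joint fit. In these, 200 of 13180 genes changed in the JQ1 group. It recovered 41.8% of changes of 1.5-fold, 68.7% of 2-fold and 97.0% of 4-fold changes. Of 151 calls 13 (8.61%) were false, and 0 of 24 unchanged lists were called. Genes were drawn independently of each other and the unchanged lists at random. The check therefore does not cover lists whose genes vary together.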

Results

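Transcript levels were measured by 3' mRNA sequencing in OPM2, an established human multiple myeloma line derived from malignant plasma cells, after 2 h with vehicle or with 1 of 3 small molecules. JQ1 occupies the bromodomains of BET proteins, which read acetylated histones,, and was given at 250 nM. BKM120 (buparlisib) inhibits the lipid kinase PI3K and was given at 1 µM. 18DS, given at 250 nM, is described by the submitters as a chimeric molecule that inhibits both PI3K and BET proteins. Each of the 4 groups (DMSO vehicle, JQ1, BKM120 and 18DS) held 3 libraries, described as biological triplicates, and no library received JQ1 and BKM120 together. Total counts per library were 5940610 to 6594995 in DMSO, 5501895 to 7692013 in JQ1, 5563788 to 6883854 in BKM120 and 5882214 to 7292895 in 18DS, and 13180 of 63152 gene identifiers passed the expression filter. At this depth the median standard error of a log2 fold change of JQ1 against DMSO was 0.169.

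The first principal component, which held 29.9% of the variance, placed the JQ1 and 18DS libraries (scores 12.1 to 32.4) apart from the DMSO and BKM120 libraries (scores -23.6 to -17.1). On the second component (18.0%) the BKM120 libraries scored -29.1 to -10.8 and the DMSO and JQ1 libraries 9.41 to 20.4. There 18DS replicate 2 scored -20.8, within the BKM120 range, and 18DS replicates 1 and 3 scored 2.08 and -5.30. The 18DS replicate 2 library also stood apart from the other 18DS libraries on the third component (26.7 against -13.7 and -9.33), which held 8.33%. The mitochondrial share of counts was 6.56% to 7.04% in DMSO and JQ1, 6.99% to 7.65% in BKM120 and 6.95% to 7.60% in 18DS. Within BKM120 and within 18DS, libraries with a higher share scored lower on the second component, 18DS replicate 2 (7.60%) included. Within DMSO and within JQ1 the library with the highest share scored highest (6.97% and 7.04%). What drives the second component was not tested. Replicates of a group differed by more than counting noise, with chi-square values of 1.92 to 8.83 per degree of freedom. Markers of other cell types were near the floor in every library. T and NK cell markers summed to 0.607 to 2.88 CPM, myeloid markers to 2.92 to 10.4 CPM, and epithelial and fibroblast markers to 8.27 to 15.04 CPM, and 0, 2 and 1 of these markers passed the filter.

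The comparison of JQ1 with DMSO asked which transcripts change within 2 h of BET inhibition. *MYC* (ENSG00000136997), the transcription factor gene often driven by enhancers in myeloma, fell by 3.53 on the log2 scale (SE 0.20, edgeR adjusted p = 6.79e-16), an 11.5-fold lower level, from 29.3 ± 2.61 to 2.54 ± 0.343 CPM (SD, n = 3). *HEXIM1* (ENSG00000186834), which encodes an inhibitor of the elongation kinase P-TEFb and is widely used as a marker of BET inhibition, rose by 1.66 (SE 0.11), from 31.4 ± 1.85 to 99.3 ± 11.2 CPM (SD, n = 3). Among genes with a mean of at least 5 CPM and no overlap between the groups' libraries, the largest rises were those of *DCUN1D3*, a regulator of cullin neddylation (log2 fold change 4.21, SE 0.23), and *SERTAD1*, a transcriptional co-regulator (3.42, SE 0.19). *CCR1*, a chemokine receptor gene (-2.37, SE 0.11), *METTL18*, a histidine methyltransferase gene (-1.77, SE 0.21), and *TFAP4*, a transcription factor gene (-1.68, SE 0.17), fell most after *MYC* among such genes.

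Of 10 tested BET inhibitor response genes, 9 rose and 0 fell with JQ1 (9 adjusted over the list alone, camera adjusted p = 1.93e-52). The list's median log2 fold change was 1.56. It shares 7 tested genes with the histone list, in which 10 of 19 rose and 0 fell (13 adjusted over the list alone, 7.47e-31), among them *H2BC21* (2.44, SE 0.14), *H2AC6* (2.09, SE 0.19) and *H2BC12* (1.37, SE 0.09). With an estimated correlation the histone list's camera adjusted p was 0.000939. Only 27 of 60 listed histone genes matched an identifier. The series measured poly(A) transcripts, so histone transcripts without a poly(A) tail are not covered. Of 60 MYC-activated genes 13 fell and 0 rose (21 fell adjusted over the list alone, 2.72e-10). Of 72 ribosome biogenesis factors 14 fell and 0 rose (23 fell adjusted over the list alone, 2.49e-11), including *RRS1* (-1.07, SE 0.11), *BRIX1* (-0.70, SE 0.10) and *UTP3* (-0.69, SE 0.08). Among 36 plasma cell and myeloma genes 12 fell and 3 rose (16 and 3 adjusted over the list alone, 9.42e-09), with falls of *IRF4*, the plasma cell transcription factor gene (-0.63, SE 0.07), the kinase gene *PIM2* (-0.53, SE 0.07) and *TENT5C* (-0.88, SE 0.11). Of 57 G2/M genes 5 fell and 0 rose (12 fell adjusted over the list alone, 9.85e-05), led by *AURKA* (-0.65, SE 0.09), and 10 fell with library totals as the only scaling.

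Of 33 sterol and fatty acid synthesis genes 5 rose and 0 fell with JQ1 (5 adjusted over the list alone, camera adjusted p = 0.0166), led by *INSIG1*, a sterol-regulated brake on lipid synthesis (1.27, SE 0.08), and the list's median of 0.03 turned to -0.001 with library totals as the only scaling. Heat shock genes (3 rose and 1 fell of 22; 7 and 2 adjusted over the list alone, 0.00159) included *DNAJB1* (0.92, SE 0.09) and *HSPA8* (0.42, SE 0.07). *BRD2*, itself a BET gene, rose by 0.91 (SE 0.08), and its list of P-TEFb and BET family genes (3 rose and 1 fell of 25; 4 and 1 adjusted over the list alone) had a camera adjusted p of 0.000937. The MAX network list (0.000514) had *MYC* as its only called member among 11 (1 rose and 2 fell adjusted over the list alone). Among 33 immediate early genes 11 rose and 2 fell (11 and 4 adjusted over the list alone, 0.00167), among them *IER5* (1.43, SE 0.09) and *JUN* (0.96, SE 0.10). This list's call was lost with an estimated correlation (adjusted p = 0.102). FOXO-activated genes (7 rose and 2 fell of 42; 8 and 4 adjusted over the list alone) had a camera adjusted p of 0.378, and 6 rose and 4 fell with library totals.

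In all, 801 genes changed with JQ1 by edgeR's quasi-likelihood test at an adjusted p under 0.05, 346 higher and 455 lower. The count was 532 with DESeq2's Wald test, 529 without DMSO replicate 3, 504 without JQ1 replicate 2 and 507 without JQ1 replicate 3. The split was 306 higher and 555 lower with library totals, and 413 higher and 379 lower with upper-quartile factors.

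**Figure D1:**
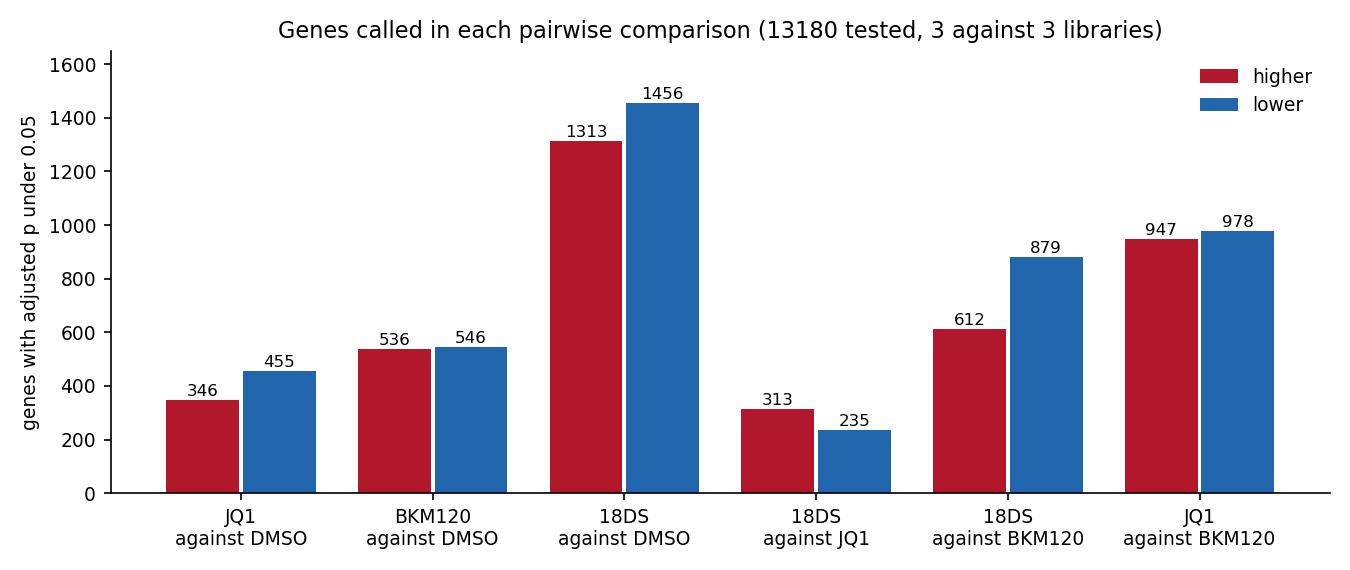
Bars give the number of genes (y axis) higher or lower in the group named first, at an edgeR adjusted p under 0.05, for the 6 pairwise comparisons of groups of 3 libraries, with 13180 genes tested. 18DS against DMSO had 1313 genes higher and 1456 lower, and 18DS against JQ1 had 313 higher and 235 lower.

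The comparison of BKM120 with DMSO asked which transcripts change within 2 h of PI3K inhibition. *KLF2* (ENSG00000127528), a transcription factor gene repressed through PI3K and AKT in lymphocytes, rose by 2.80 on the log2 scale (SE 0.16, edgeR adjusted p = 2.64e-07), from 41.9 ± 3.62 to 292 ± 23.9 CPM (SD, n = 3). *BBC3*, which encodes the pro-apoptotic protein PUMA (2.25, SE 0.21), *TP53INP1*, a stress and autophagy gene (2.13, SE 0.16), *DEPP1* (2.12, SE 0.19) and *IRS2*, an insulin receptor adaptor gene (1.53, SE 0.17), also rose. *CDKN1A*, which encodes the cell cycle inhibitor p21, fell by 1.42 (SE 0.23), and *GLIS2* fell by 1.27 (SE 0.18). *MYC* rose by 0.81 (SE 0.13), from 29.3 ± 2.61 to 51.4 ± 4.68 CPM (SD, n = 3), and *HEXIM1* differed by -0.04 (SE 0.12, adjusted p = 0.896).

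Of 42 FOXO-activated genes, which transcription factors held in the cytoplasm by AKT switch on, 20 rose and 1 fell with BKM120 (27 and 1 adjusted over the list alone, camera adjusted p = 2.29e-31), with a median of 0.48. With an estimated correlation the list's camera adjusted p was 0.000467. *KLF2*, *BBC3*, *TP53INP1*, *DEPP1*, *YPEL3* (1.85, SE 0.19) and *HBP1* (1.52, SE 0.15) are members, and *CDKN1A* was the member that fell. *PIK3IP1*, a PI3K inhibitor gene on this list, rose by 2.80 (SE 0.53) at low counts, from 0.530 ± 0.503 to 3.81 ± 0.630 CPM (SD, n = 3). Of 33 sterol and fatty acid synthesis genes 10 fell and 1 rose (10 and 1 adjusted over the list alone, 3.19e-06), including *INSIG1* (-0.81, SE 0.08), *HMGCS1* (-0.82, SE 0.13) and *MSMO1* (-0.68, SE 0.13). Ribosome biogenesis factors fell (17 of 72, 0 rose; 25 fell and 1 rose adjusted over the list alone, 2.63e-10), with *BRIX1* at -0.79 (SE 0.10) and *UTP3* at -0.74 (SE 0.08). Of 60 MYC-activated genes 9 fell and 3 rose (16 and 3 adjusted over the list alone, 0.00693), and *MYC* itself was among the 3 that rose. With library totals 15 fell and 3 rose, and with upper-quartile factors 6 fell and 3 rose.

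Heat shock genes (6 fell and 1 rose of 22; 8 and 2 adjusted over the list alone, camera adjusted p = 0.00188) included *DNAJB1* (-0.76, SE 0.09), *HSPA8* (-0.50, SE 0.07) and *DNAJA1* (-0.60, SE 0.10). Of 14 BCL2 family genes 5 rose and 0 fell (5 adjusted over the list alone, 1.27e-05), among them *BBC3*, *PMAIP1*, which encodes NOXA (0.70, SE 0.15), and *BCL2L11*, which encodes BIM (0.57, SE 0.11), and 3 rose with library totals. The BCL2 family list shares 2 tested genes with the FOXO list, *BBC3* among them. *CCND2*, the cyclin D2 gene, fell by 0.84 (SE 0.10) and *IRF4* by 0.38 (SE 0.07), while *PIM2* rose by 0.59 (SE 0.07). Histone genes (3 rose of 19, 0 fell; 4 adjusted over the list alone) and alpha and beta tubulin genes (2 fell of 11, 0 rose; 6 fell adjusted over the list alone) passed camera at 0.000269 and 0.00109. Both calls were lost with an estimated correlation (adjusted p = 0.155 and adjusted p = 0.189), and 4 tubulin genes fell with library totals. The mean and median of the tubulin genes were both below 0 (-0.25 and -0.19), and the 2 that fell were *TUBA4A* (-0.47, SE 0.07) and *TUBA1C* (-0.38, SE 0.08), whose reads could be shared with an overlapping identifier.

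In all, 1082 genes changed with BKM120 by edgeR, 536 higher and 546 lower, but the count was 532 without DMSO replicate 1, 552 without BKM120 replicate 1 and 482 without BKM120 replicate 3. The split was 439 higher and 809 lower with library totals as the only scaling, and 734 higher and 431 lower with upper-quartile factors.

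**Figure D2:**
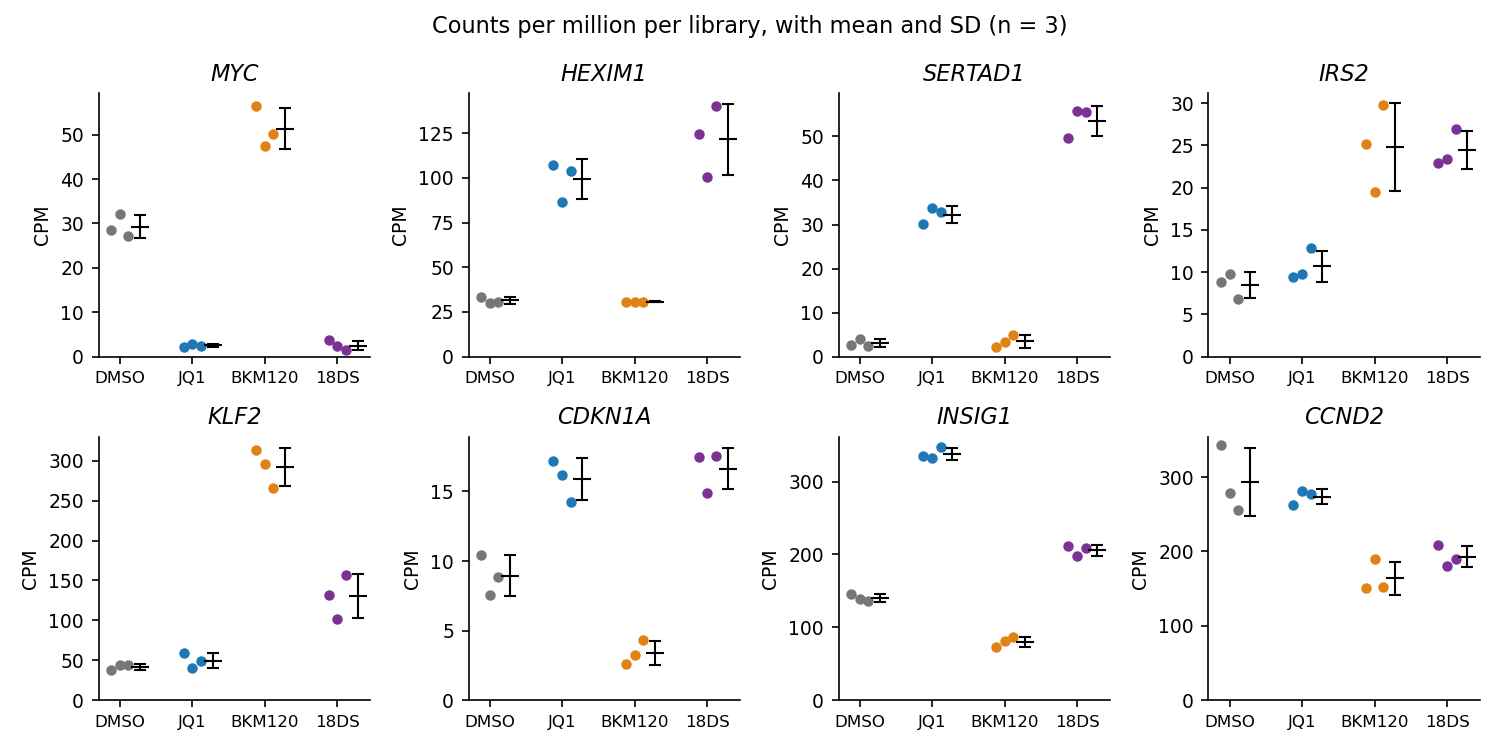
Points give CPM (y axis, from 0) of 8 genes in each of the 12 libraries, by group, and the black marks and bars give the mean and SD of 3 libraries. *MYC* stood at 2.54 CPM with JQ1 and 2.52 CPM with 18DS against 29.3 CPM with DMSO and 51.4 CPM with BKM120, and *KLF2* at 292 CPM with BKM120 and 130 CPM with 18DS against 41.9 CPM with DMSO.

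The comparison of 18DS with DMSO asked which transcripts the chimeric compound moves. *MYC* fell by 3.51 on the log2 scale (SE 0.20, edgeR adjusted p = 4.22e-16), to 2.52 ± 1.12 CPM (SD, n = 3), and *HEXIM1* rose by 1.95 (SE 0.11), to 122 ± 19.9 CPM (SD, n = 3). *DCUN1D3* (5.27, SE 0.21), *SERTAD1* (4.15, SE 0.18) and the histone gene *H3C4* (3.64, SE 0.28) rose most among genes with a mean of at least 5 CPM and no overlap between the groups' libraries. *CCR1* (-2.91, SE 0.12), *ALKBH4*, a demethylase gene (-2.71, SE 0.31), *METTL18* (-2.41, SE 0.23), *PLD6*, a mitochondrial phospholipase gene (-2.13, SE 0.21), and *KLHL9*, a ubiquitin ligase adaptor gene (-2.06, SE 0.14), fell most after *MYC* among such genes. Of the 536 genes that BKM120 raised, 267 also rose with 18DS. *KLF2* reached 130 ± 27.5 CPM and *IRS2* 24.4 ± 2.23 CPM (SD, n = 3), the latter a change of 1.52 (SE 0.17), while *PIK3IP1* stood at 0.527 ± 0.196 CPM (SD, n = 3). *CCND2* fell by 0.60 (SE 0.10).

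Of the BET inhibitor response genes 9 of 10 rose and 0 fell with 18DS (10 rose adjusted over the list alone, camera adjusted p = 5.85e-42). Of 19 histone genes 14 rose and 0 fell (15 adjusted over the list alone, 2.06e-33). Ribosome biogenesis factors fell (36 of 72, 1 rose; 42 and 1 adjusted over the list alone, 1.27e-13), with *RRS1* at -1.47 (SE 0.11), *BRIX1* at -1.18 (SE 0.11) and *UTP3* at -1.10 (SE 0.08). Of 60 MYC-activated genes 23 fell and 2 rose (27 and 4 adjusted over the list alone, 4.74e-07), including *WDR43* (-0.86, SE 0.09). With library totals 29 fell and 0 rose, and with upper-quartile factors 21 fell and 5 rose. FOXO-activated genes rose in 16 and fell in 3 of 42 cases (18 and 3 adjusted over the list alone, 3.26e-05), among them *BCL6* (2.86, SE 0.37), *IRS2* and *CDKN2D* (0.95, SE 0.13). The members that fell included the pseudokinase gene *TRIB1* (-1.17, SE 0.14). With an estimated correlation the FOXO list's camera adjusted p was 0.0463. Of 57 G2/M genes 15 fell and 0 rose (20 fell adjusted over the list alone, 0.000258), with *AURKA* at -1.05 (SE 0.09), *CCNA2* at -0.53 (SE 0.09) and *MKI67* at -0.42 (SE 0.09). With library totals 24 fell, and with upper-quartile factors 12 fell and 2 rose.

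Immediate early genes rose in 15 and fell in 6 of 33 cases with 18DS (16 and 6 adjusted over the list alone, camera adjusted p = 4.12e-06), with *IER5* at 1.68 (SE 0.09) and *JUN* at 1.52 (SE 0.10). Of 36 plasma cell and myeloma genes 14 fell and 2 rose (14 and 3 adjusted over the list alone, 0.000411), with *IRF4* at -0.67 (SE 0.07) and *KLF13* at -0.92 (SE 0.10). Heat shock genes rose in 8 and fell in 2 of 22 cases (9 and 2 adjusted over the list alone, 0.00532). Of 87 ribosomal protein and translation factor genes 41 rose and 0 fell (47 adjusted over the list alone, 6.04e-08), by a median of 0.17, led by *RPS9* (0.50, SE 0.08) and *RPL10* (0.42, SE 0.07). This call was lost with an estimated correlation (adjusted p = 0.185), and 23 rose and 1 fell with library totals as the only scaling. The sterol and fatty acid list, with 5 rising and 4 falling of 33 (5 and 5 adjusted over the list alone), had a camera adjusted p of 0.80, and with library totals its median of 0.03 turned to -0.05, with 4 rising and 8 falling. *INSIG1* was higher by 0.55 (SE 0.08) and *TM7SF2* by 1.39 (SE 0.24).

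In all, 2769 genes changed with 18DS by edgeR, 1313 higher and 1456 lower, which was 1.47 times the JQ1 and BKM120 counts added together. Without 18DS replicate 2 that ratio was 0.807, with 2085 genes for 18DS, 1021 for JQ1 and 1564 for BKM120. With each comparison fitted on its own 2 groups the counts were 2333, 1101 and 1241, which left no excess. The split of the 18DS genes was 898 higher and 2021 lower with library totals, and 1675 higher and 1213 lower with upper-quartile factors.

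**Figure D3:**
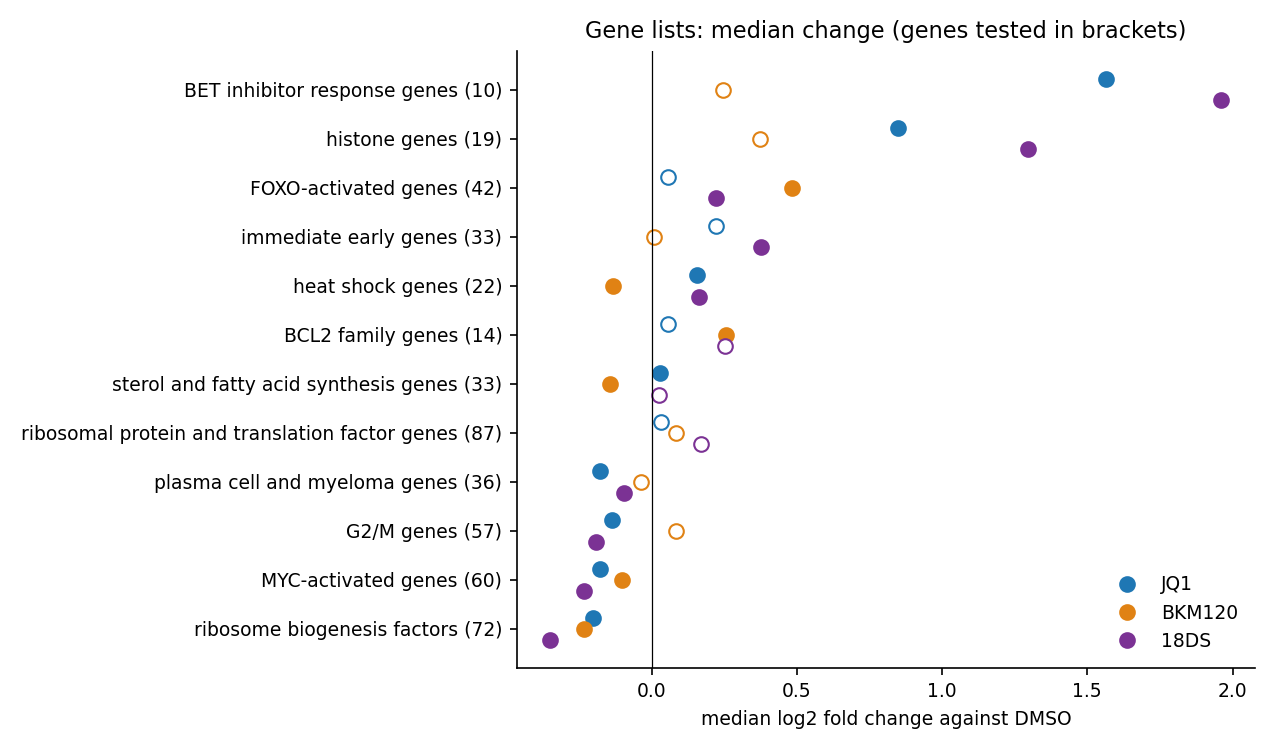
Points give the median log2 fold change against DMSO (x axis) of 12 gene lists (y axis, with the number of tested genes) for JQ1, BKM120 and 18DS, 3 libraries each; filled points have a camera adjusted p under 0.05 with an estimated correlation and open points do not. BET inhibitor response genes had medians of 1.56 with JQ1 and 1.96 with 18DS, and FOXO-activated genes 0.48 with BKM120 and 0.22 with 18DS; the sterol list's medians for JQ1 (0.03) and 18DS (0.03) turn negative with library totals, and the medians near 0 of immediate early genes and plasma cell and myeloma genes with BKM120 (0.01 and -0.04) change sign with library totals and with upper-quartile factors, respectively.

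The comparison of 18DS with JQ1, both at 250 nM for 2 h, set the chimeric compound beside the BET inhibitor at a matched dose. FOXO-activated genes stood higher with 18DS, with 8 of 42 higher and 0 lower (11 adjusted over the list alone, camera adjusted p = 5.33e-08), and 5 higher with library totals. With an estimated correlation the list's camera adjusted p was 0.0363. *DEPP1* was higher by 1.56 (SE 0.21, edgeR adjusted p = 3.57e-05), *KLF2* by 1.39 (SE 0.16), *IRS2* by 1.17 (SE 0.17) and *TP53INP1* by 1.03 (SE 0.18). *INSIG1* was lower by -0.72 (SE 0.08) and *CCND2* by -0.50 (SE 0.10), while *PIM2* (0.54, SE 0.07), *BTG1* (0.49, SE 0.08) and *JUN* (0.56, SE 0.09) were higher. For *MYC* the difference was 0.02 (95% confidence interval -0.59 to 0.63, adjusted p = 0.983), and for *IRF4* -0.04 (-0.19 to 0.10, adjusted p = 0.794).

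Some genes of the BET inhibitor response differed between the compounds at this dose. *DCUN1D3* and *SERTAD1*, picked here because both compounds raised them most, were higher with 18DS by 1.06 (95% confidence interval 0.78 to 1.35) and 0.73 (0.47 to 0.99). *HEXIM1* was higher by 0.29 (0.09 to 0.49, edgeR adjusted p = 0.0817) and *BRD2* by 0.25 (0.09 to 0.41, adjusted p = 0.0599), and neither passed. *HEXIM1* passed without an expression filter, with protein-coding genes only and without 18DS replicate 2. BET inhibitor response genes as a list stood higher (3 of 10 higher, 0 lower; 5 adjusted over the list alone, camera adjusted p = 0.000157), with *H1-2* at 0.46 (SE 0.08). Ribosome biogenesis factors stood lower (7 of 72 lower, 0 higher; 11 adjusted over the list alone, 0.000247), with 11 lower under library totals and 4 under upper-quartile factors. Histone genes (5 of 19 higher, 0 lower; 9 adjusted over the list alone) and ribosomal protein and translation factor genes (21 of 87 higher, 0 lower; 33 adjusted over the list alone) passed camera at 2.37e-08 and 5.08e-11. Both calls were lost with an estimated correlation (adjusted p = 0.0669 and adjusted p = 0.169).

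In all, 548 genes differed between 18DS and JQ1, 313 higher and 235 lower, and 27 and 13 of these by at least 2-fold. The count rested on single libraries: it was 317, 123 and 105 without JQ1 replicate 1, 2 and 3, and 1027, 215 and 159 without 18DS replicate 1, 2 and 3. With library totals the split was 208 higher and 414 lower. Of the 801 genes called in JQ1 against DMSO, 137 (17.1%) differed between 18DS and JQ1 when adjusted over those genes alone, 105 further from DMSO with 18DS and 32 closer to it. The JQ1 libraries that picked these genes also enter this test, which favours smaller 18DS changes. The share was 10.5% without JQ1 replicate 3 and 10.6% without 18DS replicate 3.

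The comparison of 18DS with BKM120 set the compounds side by side at different doses, 250 nM and 1 µM. BET inhibitor response genes stood higher with 18DS (8 of 10 higher, 0 lower; 9 adjusted over the list alone, camera adjusted p = 1.03e-44), as did heat shock genes (7 of 22 higher, 0 lower; 12 adjusted over the list alone, 7.42e-10). FOXO-activated genes stood lower (17 of 42 lower, 5 higher; 21 and 6 adjusted over the list alone, 1.34e-06), as did G2/M genes (20 of 57 lower, 0 higher; 29 adjusted over the list alone, 2.03e-10). *TP53INP1* was lower with 18DS by -1.46 (SE 0.15, edgeR adjusted p = 1.93e-09), *HBP1* by -1.28 (SE 0.14) and *BBC3* by -1.27 (SE 0.19), while *CDKN1A* was higher by 2.31 (SE 0.21). *MYC* was lower by -4.32 (SE 0.18), and *IRS2* differed by -0.01 (95% confidence interval -0.32 to 0.29, adjusted p = 0.968).

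Sterol and fatty acid synthesis genes stood higher with 18DS than with BKM120 (5 of 33 higher, 0 lower; 5 adjusted over the list alone, camera adjusted p = 1.19e-05), with *INSIG1* at 1.36 (SE 0.08) and *FASN*, the fatty acid synthase gene, at 0.40 (SE 0.07). Of the 1082 genes called in BKM120 against DMSO, 368 (34.0%) differed between 18DS and BKM120 when adjusted over those genes alone, 75 further from DMSO with 18DS and 293 less far. The BKM120 libraries that picked these genes also enter this test, which favours the smaller 18DS changes. In all, 1491 genes differed by edgeR, 612 higher and 879 lower, and 981 with DESeq2's Wald test.

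The comparison of JQ1 with BKM120 set BET inhibition at 250 nM beside PI3K inhibition at 1 µM. *MYC* was lower with JQ1 by -4.34 (SE 0.19, edgeR adjusted p = 3.17e-19), *KLF2* by -2.56 (SE 0.16), *TP53INP1* by -2.49 (SE 0.16), *BBC3* by -2.16 (SE 0.21), *BMF*, a pro-apoptotic BCL2 family gene, by -1.64 (SE 0.18) and *PIM2* by -1.12 (SE 0.07). *INSIG1* was higher by 2.08 (SE 0.08), *HSPA1B* by 2.12 (SE 0.25) and *CDKN1A* by 2.23 (SE 0.21). Sterol and fatty acid synthesis genes stood higher with JQ1 (13 of 33, 0 lower; 16 adjusted over the list alone, camera adjusted p = 1.14e-09), and G2/M genes stood lower (21 of 57, 0 higher; 25 lower and 1 higher adjusted over the list alone, 1.01e-07), as did FOXO-activated genes (20 of 42 lower, 4 higher; 22 and 4 adjusted over the list alone, 2.72e-18). In all, 1925 genes differed by edgeR, 947 higher and 978 lower, or 979 higher and 948 lower with library totals. The count was 1280 without JQ1 replicate 2, 1156 without JQ1 replicate 3, 1162 without BKM120 replicate 1 and 1171 without BKM120 replicate 3.

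Calls against DMSO were then compared between compounds. JQ1 and 18DS both raised 281 genes and both lowered 399, against 34.5 and 50.3 for independent lists, and 1 gene moved in opposite directions, against 83.6. *TRIB1*, *CCR1* and *IRF4* are among those lowered. BKM120 and 18DS both raised 267 and both lowered 316, against 53.4 and 60.3, and 37 genes moved in opposite directions, against 114. JQ1 and BKM120 both raised 38 and both lowered 111, against 14.1 and 18.8. Another 41 moved in opposite directions, against 32.8 for independent lists, among them *MYC*, *INSIG1*, *PIM2*, *CDKN1A*, *DNAJB1* and *HSPA8*. The covariance of log2 fold changes across genes was 0.165 for JQ1 and 18DS, 0.0936 for BKM120 and 18DS and 0.0506 for JQ1 and BKM120, against 0.0281, 0.0280 and 0.0280 in 100 simulations of unchanged groups that shared 3 simulated DMSO libraries (correlations 0.768, 0.481 and 0.327 against 0.499, 0.496 and 0.496). The simulated genes varied independently, so variation that moves genes together in the real DMSO libraries is missing from these references.

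The 3 control libraries cannot be split into parts of at least 2, so part of the excess over independent lists may come from the shared controls. The 680 genes shared by JQ1 and 18DS were 451 without JQ1 replicate 2. The 583 shared by BKM120 and 18DS were 252 without DMSO replicate 1, 304 without BKM120 replicate 1 and 269 without BKM120 replicate 3. The 149 shared by JQ1 and BKM120 were 91 and 95 without DMSO replicate 1 and 2, 97 without JQ1 replicate 2, and 98 and 94 without BKM120 replicate 1 and 3.

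Contrasts with no library in common gave a further comparison. Of the 1082 genes called in BKM120 against DMSO, 980 (90.6%) had the same sign in 18DS against JQ1, and across all tested genes, which are not independent replicates, the correlation was 0.344. Of the 801 genes called in JQ1 against DMSO, 770 (96.1%) had the same sign in 18DS against BKM120, with a correlation of 0.585.

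**Figure D4:**
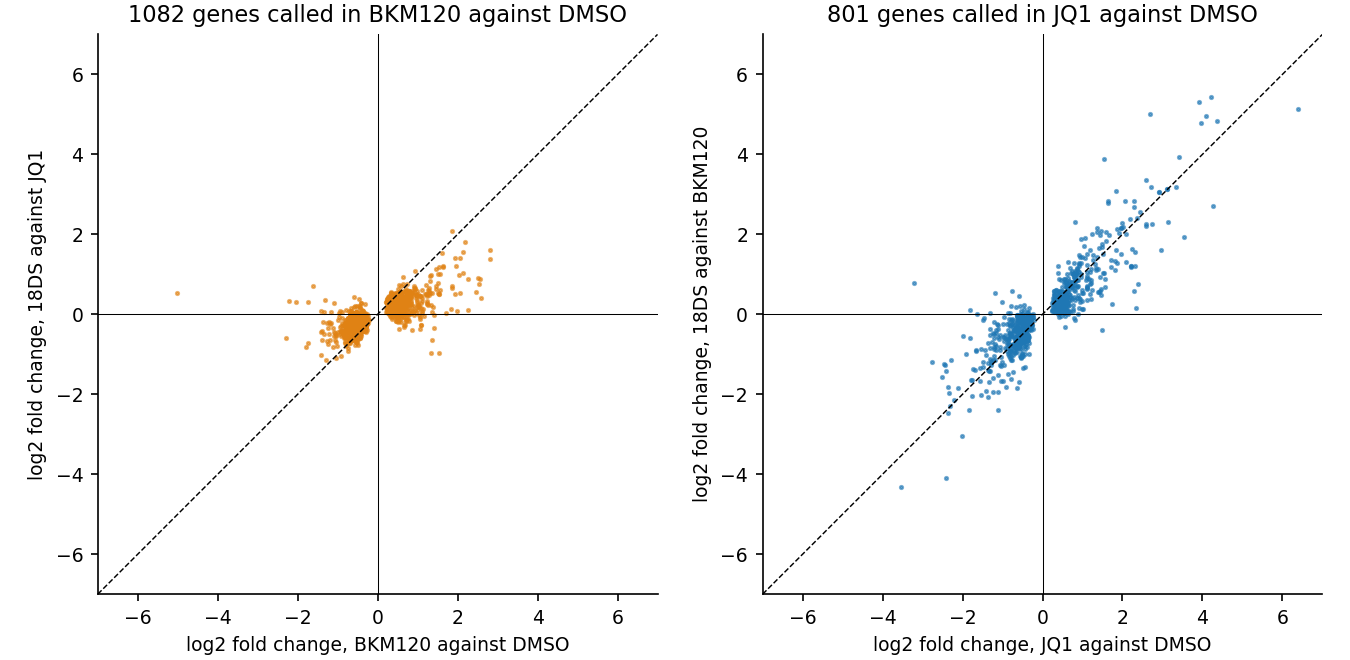
Each point is a gene, and both axes are log2 fold changes; the left panel sets 18DS against JQ1 (y axis) beside BKM120 against DMSO (x axis) for the 1082 genes called in the latter, the right panel 18DS against BKM120 beside JQ1 against DMSO for 801 genes, and the dashed line marks equal changes. Of the points, 980 on the left and 770 on the right have the same sign on both axes; the genes were picked by their x values, which overstates those.

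The last comparison asked whether the 18DS change differed from the sum of the JQ1 and BKM120 changes on the log2 scale, at these doses. *ST3GAL6*, a sialyltransferase gene, departed by -0.85 (SE 0.14, edgeR adjusted p = 0.00209), with 35.4 ± 1.28 CPM in DMSO, 25.2 ± 0.394 in JQ1, 91.5 ± 2.93 in BKM120 and 36.2 ± 0.722 in 18DS (SD, n = 3). *RBMS1*, an RNA-binding protein gene (-0.88, SE 0.14), and *CCDC117* (-0.87, SE 0.14) also lay below the sum. *KLF2* lay furthest below it among called genes (-1.41, SE 0.22, edgeR adjusted p = 0.0321). *CDKN1A* lay above it by 1.496 (SE 0.28, adjusted p = 0.0145), at 8.95 ± 1.45 CPM in DMSO, 15.9 ± 1.5 in JQ1, 3.38 ± 0.876 in BKM120 and 16.6 ± 1.49 in 18DS (SD, n = 3), a call that was lost without DMSO replicate 3 and without BKM120 replicate 1. FOXO-activated genes lay below the sum, by a median of -0.32 (1 higher and 1 lower of 42; 1 and 9 adjusted over the list alone, camera adjusted p = 4.57e-10), with 1 higher and 3 lower under upper-quartile factors. Heat shock genes lay above it, by a median of 0.16 (1 higher of 22, 0 lower; 3 adjusted over the list alone, 1.47e-05). With an estimated correlation the camera adjusted p of both lists was 0.0172. Lists with 0 called genes also departed as lists (0 adjusted over the list alone). Sterol and fatty acid synthesis genes (median 0.12, camera adjusted p = 0.00383), ribosome biogenesis factors (0.08, 0.00333) and MYC-activated genes (0.10, 0.0188) lay above the sum, and G2/M genes (-0.16, 0.000474) below it.

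In all, 16 genes departed from the sum by edgeR, 9 higher and 7 lower, with 1015 at an unadjusted p under 0.05. *RIOX1* (0.71, SE 0.14) and the unnamed identifier ENSG00000255242, both among the 9, had the same counts in each of the 12 libraries, so they are not separate signals. With upper-quartile factors the split was 9 higher and 14 lower. Without DMSO replicate 3 the split was 0 higher and 3 lower, so each call above the sum, *RIOX1* and the heat shock gene *HSPA8* included, was lost there. Thinning to the smallest total gave 9 higher and 11 lower. The count was 45 without an expression filter, 8 with limma-voom, 10 without robust dispersions and 29 with protein-coding genes only. It was 7 and 3 without DMSO replicate 2 and 3, 8, 6 and 10 without JQ1 replicate 1, 2 and 3, 5 and 6 without BKM120 replicate 1 and 3, and 26, 31 and 8 without 18DS replicate 1, 2 and 3.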

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

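The tests of the ribosomal protein list, and the margin of 2 standard errors used for them, were chosen only after its result was seen, and the other tests here were chosen before.

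JQ1 and BKM120, each against DMSO, called 41 genes in opposite directions, against 32.8 for independent lists. They drew attention because they also differed in the direct test of JQ1 against BKM120, but that adds no separate support, since genes called in opposite directions against the same DMSO libraries will nearly always differ there. Of these, 18 were higher with JQ1 and lower with BKM120, among them *INSIG1*, *FASN*, *HSPA8*, *DNAJB1* and *CDKN1A*, and 23 were the reverse, among them *MYC*, *PIM2*, *FBXO32* and *TNFRSF17*. *FBXO32*, a ubiquitin ligase gene, fell by 2.37 on the log2 scale with JQ1 and rose by 1.61 with BKM120. It is not among the largest falls with JQ1 named above. It did not have both a mean of at least 5 CPM and no overlap between those groups' libraries. These genes other than those the naming rule covers were picked after their values were seen.

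For 16 genes the 18DS change differed from the JQ1 and BKM120 changes added together at the test's threshold, and 2 of these, *RIOX1* and ENSG00000255242, are identical in their values. Of 100 regroupings of the libraries, 5 gave as many genes, the real grouping included, and the highest of the others gave 491. By the criterion set beforehand, a share of 0.05 or more, chance is not excluded for this count. These regroupings mix the 4 treatments, so they are no clean reference for it. For the 6 pairwise comparisons the 10 splits of the libraries are too few for a share under 0.05, and 1 of the 10, the real one, gave as many genes in each. The real counts were 801, 1082, 2769, 548, 1491 and 1925 for JQ1, BKM120 and 18DS against DMSO, 18DS against JQ1, 18DS against BKM120 and JQ1 against BKM120. The highest counts of the other splits were 2, 0, 0, 0, 85 and 0. These splits mix the 2 treatments on each side, which widens the spread and lowers their counts, so they are no clean reference either.

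18DS had 1.47 times as many called genes against DMSO as JQ1 and BKM120 together. Depth alone is argued against, since the lowest ratio over 5 thinnings to equal totals was 1.44, and so are the composition factors, since the lowest ratio over 3 other scalings was 1.38. The excess was lost without 18DS replicate 2, where the ratio was 0.807. There 18DS had 2085 calls, near the 2137 without 18DS replicate 3. JQ1 calls rose from 801 to 1021 and BKM120 calls from 1082 to 1564, so the ratio does not show that this library made the 18DS calls. The excess was also lost with each comparison fitted on its own 2 groups, where 18DS had 2333 calls, JQ1 1101 and BKM120 1241. A BKM120-like response added to a JQ1-like one may contribute to the 18DS calls, since 18DS minus JQ1 and BKM120 minus DMSO, which share no library, correlated across genes at 0.344 (0.243 to 0.344 with each library left out). The excess itself is therefore not held to be biological.

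FOXO-activated genes rose less with 18DS than the JQ1 and BKM120 changes added together, by a median of -0.32, which a weaker PI3K response to 18DS at 250 nM than to BKM120 at 1 µM might account for. Over genes that BKM120 lowered, 18DS minus JQ1 was on average 0.658 of BKM120 minus DMSO, measured in libraries not used to pick the genes, but only 7 of 9 held-out pairs lay below 1 (0.381 to 1.15), which leaves it open. Both exceptions (1.15 and 1.08) held out BKM120 replicate 2, and the 6 pairs with BKM120 replicate 1 or 3 lay at 0.381 to 0.619. A damping limited to genes that BKM120 raised also stays open, since the raised ratio lay below the lowered one by a mean of -0.0371, in 7 of 9 pairs. Lists that BKM120 lowered lay above the sum, sterol genes by a median of 0.12, ribosome biogenesis factors by 0.08 and MYC-activated genes by 0.10. These values cannot decide against such a damping, since JQ1 moved each of these lists too. The BKM120 and DMSO libraries that showed the lists as lowered also enter the sum, which favours a place above it.

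Ribosomal protein and translation factor genes stood higher with 18DS than with DMSO, by a median of 0.169. One library alone is argued against, since the lowest median without any 18DS or DMSO library was 0.148. The composition factors stay open for the size of this rise against DMSO. With library totals the list's median was 0.0977, which lay past the bound that argues against them, but by less than 2 standard errors (SE 0.0460), and without that later margin they would have been excluded. Library totals moved the median of all genes too, by -0.0719, so this test does not bear on the list's place relative to other genes. Variation that moves these genes together between libraries also stays open, and might be a source of the rise, since the largest difference between libraries of a group was 0.695 of the difference between 18DS and DMSO. No biological explanation was tested.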

How the results depend on the processing

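Leaving out single libraries for list tests, overlaps and shares, using protein-coding genes alone and the filter of 5 CPM in 6 libraries were chosen only after results were seen, and the other alternatives were planned. No result reversed its direction past the threshold. Of 559 results for 232 named genes (514 called), DESeq2's Wald test, which gave a value for 539, ended 26 calls and added 3, library totals ended 20 and added 2, and leaving out JQ1 replicate 2 ended 73. Of 175 list results (86 called), an estimated correlation ended 31. A gene or list called in neither setting counts as unchanged even where its sign turned, and genes without an adjusted p in DESeq2 gave no value. The filter of 1 CPM in 6 libraries was planned as stricter but kept more genes. Scalings moved the median of all genes by at most -0.0719 (library totals, 18DS against DMSO). At this depth 41.8% of simulated 1.5-fold changes were recovered. A group left with 2 libraries shares the spread of the others.

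Counts moved by over 1.5 times as follows, and the cause was not tested. DESeq2's Wald test gave 532 genes for JQ1 against DMSO (801) and 981 for 18DS against BKM120 (1491). For departures from the sum (16) the count was 45 without an expression filter, 8 with limma-voom, 10 without robust dispersions and 29 with protein-coding genes alone. With an estimated correlation, passing lists numbered 6 of 14 for BKM120 and 9 of 14 for 18DS against DMSO, 3 of 9 for 18DS against JQ1 and 10 of 16 for 18DS against BKM120. At an adjusted p under 0.01 the shared calls were 372 (680) for JQ1 and 18DS, 224 (583) for BKM120 and 18DS and 59 (149) for JQ1 and BKM120.

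With each library left out in turn, called genes numbered 504 (without JQ1 replicate 2) to 1021 (without 18DS replicate 2) for JQ1, 482 (without BKM120 replicate 3) to 1564 (without 18DS replicate 2) for BKM120 and 1909 to 3026 for 18DS against DMSO. They numbered 105 (without JQ1 replicate 3) to 1027 (without 18DS replicate 1) for 18DS against JQ1, 1028 to 1544 for 18DS against BKM120, 1156 (without JQ1 replicate 3) to 2316 (without 18DS replicate 2) for JQ1 against BKM120, and 3 (without DMSO replicate 3) to 31 (without 18DS replicate 2) for departures from the sum. Passing lists numbered 11 to 13, 9 (without BKM120 replicate 2) to 14, 11 to 14, 7 to 10, 14 to 17, 13 to 15 and 8 to 11 in the same order. Shared calls ran from 451 (without JQ1 replicate 2) to 775 for JQ1 and 18DS, 252 (without DMSO replicate 1) to 743 for BKM120 and 18DS, and 91 (without DMSO replicate 1) to 220 for JQ1 and BKM120. The share of JQ1-called genes that differed between 18DS and JQ1 ran from 10.5% (without JQ1 replicate 3) to 20.9%, and that of BKM120-called genes from 26.4% to 50%.

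The labels do not say that replicate numbers pair the libraries. Of 18 correlations between libraries of the same number, 0 were over 0.1 (-0.128 to 0.0919, against -0.118 to 0.148 for other numbers). With a replicate block the counts, in the same order, were 743, 1042, 2667, 522, 1445, 1827 and 16, and passing lists 11, 14, 15, 9, 17, 15 and 9.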

Other observations

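Leaving out single libraries for the gene list tests was chosen only after results were seen, and the list tests themselves were chosen before.

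Genes of the p53 response moved both ways with each compound. With 18DS, *SESN2*, a stress-induced regulator of mTORC1 (log2 fold change 1.85, SE 0.12), and *PMAIP1* (1.00, SE 0.14) rose, while *AEN*, an apoptosis-linked nuclease gene (-1.75, SE 0.13), and *MDM2*, which encodes the ubiquitin ligase of p53 (-0.87, SE 0.12), fell. Of 24 p53 target genes 8 rose and 3 fell with 18DS (9 and 3 adjusted over the list alone, camera adjusted p = 0.0311), a call lost with an estimated correlation (adjusted p = 0.101) and without 18DS replicate 1 (0.0829), DMSO replicate 2 (0.0777) or BKM120 replicate 2 (0.0514). With BKM120, 6 rose and 3 fell (8 and 4 adjusted over the list alone, 0.0197), a call lost with an estimated correlation (adjusted p = 0.111) and without BKM120 replicate 2 (0.0664) or DMSO replicate 2 (0.0632). With JQ1, 3 rose and 2 fell (4 and 3 adjusted over the list alone, 0.215). The p53 list shares 5 tested genes with the FOXO list and 3 with the BCL2 family list. Of 14 BCL2 family genes 6 rose and 1 fell with 18DS (7 and 2 adjusted over the list alone, 0.0431), the one that fell being *BMF* (-1.12, SE 0.18), and 4 rose and 2 fell with library totals. That call was lost with an estimated correlation (adjusted p = 0.101), with library totals (0.0551) and without 18DS replicate 1 (0.0775) or 3 (0.0505) or DMSO replicate 1 (0.0538) or 3 (0.0533).

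BKM120 raised genes of the PI3K pathway itself, with 4 of 39 higher and 0 lower (4 adjusted over the list alone, camera adjusted p = 0.0225). They were *IRS2*, *RICTOR*, an mTORC2 subunit gene (0.82, SE 0.13), *PIK3CA*, a PI3K catalytic subunit gene (1.06, SE 0.20), and *PIK3C2A*. The list's call was lost with an estimated correlation (adjusted p = 0.118). It shares 4 tested genes with the FOXO list, *IRS2* among them, so the 2 lists are not separate results. Of 26 glycolysis and hypoxia genes 3 fell and 0 rose with BKM120 (4 and 1 adjusted over the list alone, 0.0368), led by *PFKFB3*, a glycolytic regulator gene (-0.92, SE 0.12), and the hexokinase gene *HK2* (-0.55, SE 0.11), and 5 fell with library totals. That call was lost with an estimated correlation (adjusted p = 0.189) and without BKM120 replicate 2 (0.0664) or 3 (0.122). Of 57 G2/M genes 5 rose and 0 fell with BKM120 (6 adjusted over the list alone, 0.0229), among them *NUF2* (0.36, SE 0.08), a call lost with an estimated correlation (adjusted p = 0.157) and without BKM120 replicate 2 (0.0664) or DMSO replicate 3 (0.0704). Ribosomal protein and translation factor genes (15 of 87 rose and 0 fell, 20 and 2 adjusted over the list alone, 0.00693, with 9 rising and 3 falling under library totals) lost their call with an estimated correlation (adjusted p = 0.515) and without BKM120 replicate 2 (0.0664) or DMSO replicate 1 (0.0778). Immediate early genes (9 rose and 5 fell of 33, 9 and 8 adjusted over the list alone, 0.0200) lost theirs with an estimated correlation (adjusted p = 0.189) and without BKM120 replicate 2 (0.0542) or DMSO replicate 2 (0.0632).

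The next lists held called genes without passing as a list in the comparison named. ERK feedback genes had 1 rise and 5 falls of 15 with JQ1 (2 and 5 adjusted over the list alone, camera adjusted p = 0.0674), including falls of the phosphatase gene *DUSP4* (-0.88, SE 0.09) and the signalling inhibitor gene *SPRY1* (-1.75, SE 0.29). NF-kB target genes had 1 rise and 6 falls of 19 with 18DS (2 and 7 adjusted over the list alone, 0.194), including *TNFAIP8* (-0.94, SE 0.16) and *BCL3* (-0.70, SE 0.16). Unfolded protein response genes had 6 rises and 3 falls of 26 with 18DS (6 and 3 adjusted over the list alone, 0.453), or 4 and 4 with library totals and 7 and 2 with upper-quartile factors. Among them were a fall of *XBP1*, a plasma cell secretory regulator (-0.53, SE 0.08), and a rise of the chaperone gene *CALR* (0.46, SE 0.09). ATF4 target genes had 5 rises and 6 falls of 36 (6 and 7 adjusted over the list alone, 0.265), or 6 and 5 with upper-quartile factors, with *CHAC1* at 1.95 (SE 0.34). G1/S and DNA replication genes had 8 rises and 11 falls of 53 (8 and 11 adjusted over the list alone, 0.193), or 4 and 13 with library totals and 10 and 11 with upper-quartile factors, with *E2F2* at -0.83 (SE 0.09) and *CDC25A* at -0.89 (SE 0.12). Interferon-stimulated genes had 2 rises and 3 falls of 16 (2 and 3 adjusted over the list alone, 0.815).

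Oxidative phosphorylation genes passed with 18DS (16 rose and 2 fell of 70, 19 and 2 adjusted over the list alone, camera adjusted p = 0.0431). With library totals 7 rose and 4 fell, and with upper-quartile factors 24 rose and 1 fell. For this list the median of 0.06 turned to -0.01 with library totals and the call was lost with an estimated correlation (adjusted p = 0.267), with library totals (0.202) and without 18DS replicate 1 (0.0524) or 3 (0.0505), BKM120 replicate 2 (0.0514) or DMSO replicate 2 (0.0640). MAX network genes passed with 18DS (2 rose and 3 fell of 11, 2 and 3 adjusted over the list alone, 0.0453), a call lost with an estimated correlation (adjusted p = 0.101) and without 18DS replicate 2 (0.0550) or 3 (0.0941), BKM120 replicate 2 (0.0522) or 3 (0.0512) or DMSO replicate 3 (0.0533).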
